A study of Swertia japonica with 2 samples.

How the data were processed

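Total RNA of aerial tissues and roots of Swertia japonica plants 6 months old was used for strand-specific, poly(A)-selected cDNA libraries, 1 library per tissue, per the labels' protocols. Trimmomatic and RSEM are named in the submitters' processing notes, without versions. RSEM estimates how many reads come from each transcript. The assembler, the aligner, their settings and the redundancy filter are not given in the sources used here.

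Each library file gives, per the file headers, the length, effective length, expected count, TPM, FPKM and isoform percentage of 81729 assembled transcripts. The expected counts deposited by the authors are not normalised, and all of them are whole numbers (0 non-whole values in either library). Reads split in fractions between similar transcripts usually give counts that are not whole, so the whole counts argue against such splitting. It is open whether reads matching several transcripts were assigned to 1 of them or left out. The counts of similar transcripts, zeros included, are uncertain for this reason. The TPM values deposited by the authors are scaled by effective length to a fixed sum per library, and the FPKM values deposited by the authors to effective length and the number of counted reads. The isoform percentage deposited by the authors is 0 or 100 throughout, because each of the 81729 transcripts has a gene identifier of its own. A series table deposited by the authors pairs each transcript with a unigene number and gives a second set of FPKM values, whose making is not given in the sources used here. Its root column was matched to the root sample by name. The other 1 column of per-sample values in it is named for leaf, which no sample label says, and was not used. Short transcripts have a small effective length, so a few reads give a high FPKM or TPM.

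Roots were compared with aerial tissues by the ratio of CPM, each count scaled to its library's total expected count. Unigenes with at least 20 counts over both libraries were compared, a count under 3 was set to 3 before the ratio was taken, and a difference of at least 4-fold was called. With 1 library per tissue no test across samples was possible and no p-value was computed. For each ratio a 95% exact (Clopper-Pearson) interval was computed from the division of the reads between the libraries. Intervals and floors cover counting error only, since reads without molecular identifiers are not independent molecules, and they leave out differences between plants. Total depth was 5351257 counts in aerial tissues and 4207068 in roots, which gave a median interval half-width of 2.34-fold for unigenes with at least 20 and under 50 counts. Shares by length carry 95% Wilson intervals. Intervals of shares and of ratios between shares treat unigenes as independent, which forms of 1 gene are not, so they may be too narrow.

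The named unigenes are the 2 per direction with the largest fold at the near end of the interval, a rule fixed before the data were examined for unigenes without gene names; the most abundant unigene of each library is given without its identifier. The comparison, its thresholds, the main alternatives and 14 lists of pathway and marker genes were fixed at the same time. The lists could not be matched to unigenes without names and were not analysed here.

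The fold calls were tested on simulated data with 81729 unigenes at the real depth. The changed unigenes were drawn from those with at least 100 counts over both libraries. All 50 changed 8-fold, all 50 changed 16-fold and all 50 changed 32-fold were called, and 0 of 50 changed 2-fold. Of the 33422 compared unigenes without a change, 27 were called. The draws held counting error only, and changes in unigenes with fewer counts were not simulated. Counting noise was measured by dividing each unigene's reads at random between the libraries, 20 times. Pairs of unigenes of 1 TR gene were set against 1000 random pairings in which the second member was replaced by a unigene of similar count. Alternatives covered scaling by edgeR's TMM (edgeR 4.0.16) and DESeq2 size factors (DESeq2 1.42.0), count minimums, folds, FPKM with pseudocounts of 1 and 0.1, a length minimum of 500 bases, and thinning of the deeper library. Computations used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3, and R 4.3.3.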

Results

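Swertia japonica is a bitter medicinal herb of the gentian family that accumulates secoiridoid glycosides and xanthones. Poly(A)-selected RNA of plants 6 months old was sequenced from 2 parts of the plant, the aerial tissues and the roots, with 1 library each. No genome was used here: reads were assigned to 81729 transcripts assembled de novo, called unigenes, which together span 72.2 megabases. Unigene length had a median of 537 bases and reached 12347 bases, and 38597 unigenes (47.2%) were under 500 bases. The aerial library held 5351257 expected counts and the root library 4207068. The series title gives the purpose as finding genes that could make the plant's therapeutic metabolites, and the design implies 1 comparison, roots against aerial tissues. With 1 library per tissue there was no replicate check, so every difference below describes these 2 libraries; no p-value is given, and each interval covers counting error only. The files used here pair the unigenes with no gene names or functions, so transcripts are grouped by abundance, tissue bias, length and identifier, and no pathway is named.

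Most of the assembly was detected in both parts of the plant, at low depth. Of the 81729 unigenes, 8726 (10.7%) were at 0 in aerial tissues and 9466 (11.6%) at 0 in roots, while 1259 were at 0 in both. A count of 0 allows up to 3 counts, or 0.561 CPM in aerial tissues and 0.713 in roots. The median unigene had 6 counts in aerial tissues and 5 in roots. An FPKM of at least 1 was reached by 69286 unigenes in aerial tissues and 69260 in roots. Of these, 35375 (51.1%) in aerial tissues and 37199 (53.7%) in roots rested on fewer than 10 counts. For unigenes of the shortest length, a single count already gave an FPKM of 5.35 in aerial tissues and 6.83 in roots. Unigenes with both an FPKM of at least 1 and at least 10 counts numbered 33911 in aerial tissues and 32061 in roots.

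The aerial library was more concentrated in a few transcripts than the root library. Its 100 most abundant unigenes held 20.6% of the TPM, against 16.4% for the 100 most abundant in roots. The 10 most abundant held 6.34% in aerial tissues and 4.85% in roots. It took 1794 unigenes to reach 50% of the TPM in aerial tissues and 2398 in roots. The most abundant unigene of the aerial library, 1002 bases long, stood at 15826 TPM there and 657 TPM in roots, from 68785 and 2385 counts, a 22.7-fold difference in CPM (95% exact interval 21.8 to 23.6). The most abundant unigene of the root library, 660 bases long, stood at 9760 TPM in roots and 1767 TPM in aerial tissues, from 20690 and 4488 counts, a 5.86-fold difference (95% exact interval 5.68 to 6.06).

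The leading transcripts of the 2 libraries were largely different. Among the 100 most abundant unigenes of each library, 20 were shared. Of the aerial 100, 69 were at least 4-fold higher in aerial tissues, 1 was at least 4-fold higher in roots and 30 differed by less. Of the root 100, 42 were at least 4-fold higher in roots, 1 was at least 4-fold higher in aerial tissues and 57 differed by less. The aerial 100 carried 20.6% of the aerial TPM and 5.94% of the root TPM, whereas the root 100 carried 16.4% of the root TPM and 7.77% of the aerial TPM. Each list was chosen by TPM in its own library, which by itself favours higher values there. The lists came closer further down: the 1000 most abundant unigenes shared 535 members, and 341 of the aerial 1000 and 173 of the root 1000 were at least 4-fold higher in their own library. Across all unigenes, which are not independent replicates, the log2(FPKM + 1) values of the libraries correlated with Pearson's r = 0.51, and with r = 0.64 over the unigenes with at least 20 counts.

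Between roots and aerial tissues, 33536 unigenes (41.0%) had at least 20 counts over both libraries and were compared. Of these, 2787 (8.31%) were at least 4-fold higher in aerial tissues and 2124 (6.33%) at least 4-fold higher in roots, while 21800 (65.0%) lay within 2-fold. The aerial-higher set made up 29.7% of the aerial TPM and 1.79% of the root TPM. The root-higher set made up 17.0% of the root TPM and 2.10% of the aerial TPM. Differences of at least 16-fold were found for 539 aerial-higher and 333 root-higher unigenes. The whole 95% exact interval lay past 4-fold for 1543 aerial-higher and 1015 root-higher unigenes. Drawing both libraries from equal expression at the same depth gave a mean of 14.1 aerial-higher and 4.95 root-higher unigenes over 20 draws. Counts were scaled to library totals, which left the median log2 ratio of the compared unigenes at 0.27 in favour of roots. TMM factors removed that shift and gave 3294 aerial-higher and 1700 root-higher unigenes, and DESeq2 size factors computed over unigenes with at least 20 counts gave 3300 and 1698. The root-higher share of the biased unigenes was 43.2% with library totals and 34.0% with either of these. DESeq2 size factors over all unigenes came out at 1.00 for both libraries, which leaves the counts unscaled for depth, and gave 3523 and 1610, a share of 31.4%. With library totals, the excess of aerial-higher over root-higher unigenes did not hold at 2-fold, where 5338 were aerial-higher and 6398 root-higher. With unigenes of at least 5 counts included the numbers were 2948 and 3093, but at such counts the floor of 3 is a higher CPM in roots than in aerial tissues and admits root-higher unigenes at fewer counts.

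**Figure D1:**
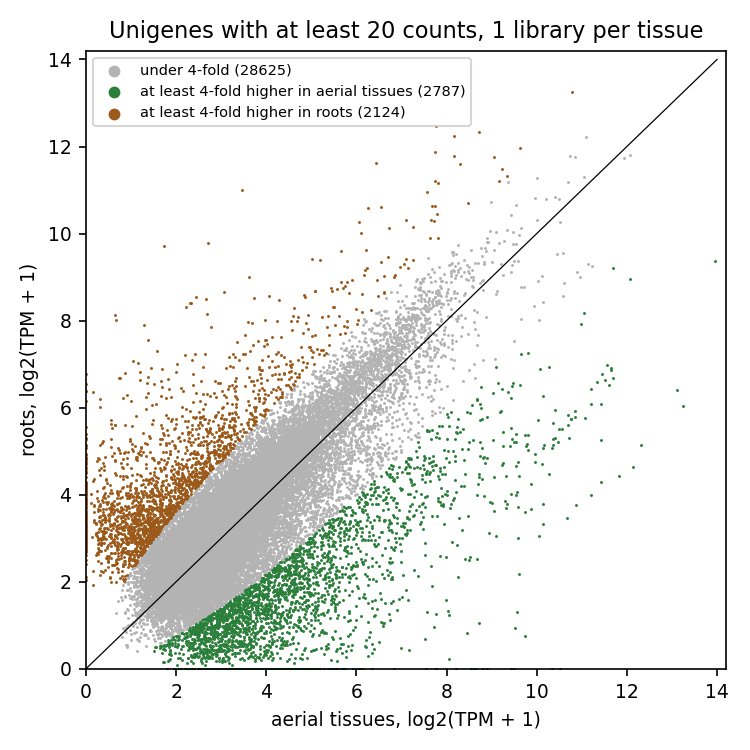
Each point is 1 of the 33536 unigenes with at least 20 counts, placed by log2(TPM + 1) in the aerial library (x axis) and the root library (y axis); the line marks equal TPM. Green points are the 2787 unigenes at least 4-fold higher in aerial tissues and brown points the 2124 at least 4-fold higher in roots, both by CPM, and the aerial-higher set reaches the highest abundances.

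The named unigenes are those with the largest fold at the near end of the interval, a rule that favours high counts. Unigene47044 (1561 bases) had 10734 counts, or 1471 TPM, in aerial tissues and 0 counts in roots. It was 2813-fold higher in aerial tissues with roots set to the floor of 3 counts, and the near end of its 95% exact interval was 2287-fold. Unigene47043 (1361 bases) had 8087 aerial counts, or 1295 TPM, and 0 root counts, 2119-fold higher at the same floor, with a near end of 1723-fold. Both carry the identifier of 1 assembled gene as alternative forms. Whether reads matching both were assigned to 1 of them or left out is unknown, so the size of each count is uncertain. Assignment to 1 of these 2 forms would not leave both at 0 in roots, and both were also at 0 in the second set of root FPKM values. Whether root reads matching both forms were left out is not known. In the other direction, Unigene42163 (666 bases) had 1787 counts, or 833 TPM, in roots and 6 counts in aerial tissues, 379-fold higher in roots (95% exact interval 174 to 1034). Its identifier also marks it as a numbered form of an assembled gene, so its counts may carry the same doubt. Unigene20578 (893 bases) had 6482 root counts, or 2059 TPM, and 38 aerial counts, 217-fold higher in roots (95% exact interval 158 to 307). It ranked 25 by TPM in roots and 14033 in aerial tissues.

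Transcripts seen in 1 part of the plant alone were more numerous in aerial tissues, by less at equal depth. With at least 20 counts in one library, 301 unigenes were at 0 in roots and 146 at 0 in aerial tissues. The aerial library is deeper, which favours the aerial side in such counts. With the aerial library thinned to the root total the numbers were 254 and 177. The 301 had a median of 38 aerial counts, and against the floor of 3 root counts the median difference was 9.96-fold. The 146 had a median of 31 root counts and a median difference of 13.1-fold against the floor of 3 aerial counts. Unigenes with at least 100 counts in one library and 0 in the other numbered 49 for aerial tissues and 11 for roots. The highest count beside a 0 was 10734 in aerial tissues and 304 in roots.

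The biased share differed between classes of total count, which grows with both abundance and length, and showed no steady trend. Of the 3430 unigenes with at least 500 counts, 495 (14.4%) were aerial-higher and 206 (6.01%) root-higher. Of the 10148 unigenes with at least 20 and under 50 counts, 835 (8.23%) were aerial-higher and 892 (8.79%) root-higher. In between, the aerial-higher share was 7.27% of the 7273 unigenes with at least 50 and under 100 counts and 7.32% of the 12685 with at least 100 and under 500, and the root-higher share 5.80% and 4.76%. The precision differed as well: the median half-width of the 95% exact interval was 2.34-fold in the lowest of these classes and 1.16-fold in the highest.

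Root-higher unigenes were shorter than the others. Their median length was 1038 bases, against 1272 for aerial-higher unigenes and 1409 for those under 4-fold. The root-higher share fell from 19.3% of the 171 compared unigenes under 300 bases to 9.59% of the 8568 of at least 500 and under 1000 bases and 2.64% of the 7950 of 2000 bases and over. The aerial-higher share in the same classes was 9.36%, 9.40% and 6.06%. The median log2 ratio of roots over aerial tissues was 0.35, 0.35 and 0.20 in these classes.

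**Figure D2:**
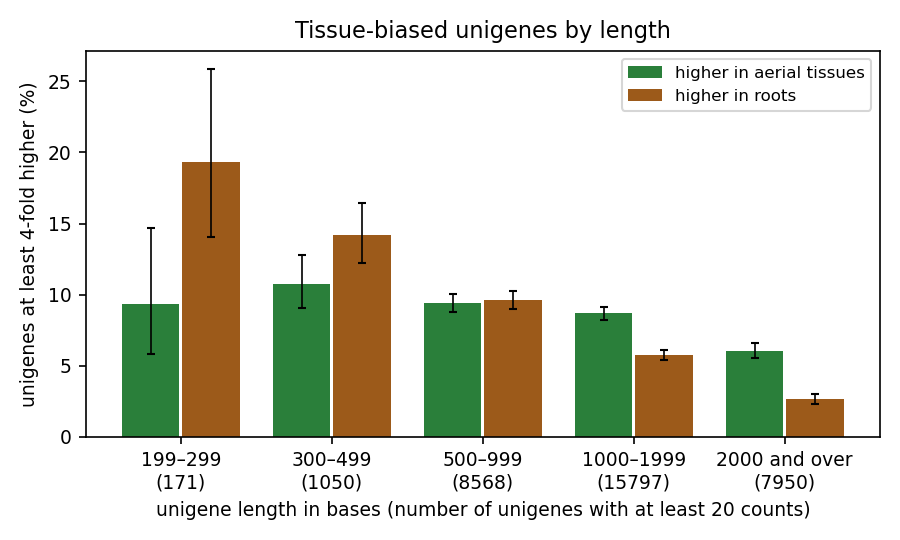
Bars give the percentage of compared unigenes (at least 20 counts) that were at least 4-fold higher in aerial tissues (green) or in roots (brown), by unigene length in bases, with the number of unigenes in brackets; error bars are 95% Wilson intervals over unigenes. The root-higher share falls with length from 19.3% to 2.64%, and the aerial-higher share lies between 6.06% and 10.8%.

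The identifiers of the unigenes took several forms. Those starting with TR, with component, gene and isoform numbers, covered 41426 unigenes and 54.1% of the aerial and 54.8% of the root counts. Contigs whose identifiers carry the words Swertia and Leaf covered 28277 unigenes, those starting with C 8190 and scaffolds 3836. The aerial-higher share was 8.75% for the TR form, 7.99% for the leaf-named contigs, 6.99% for the C form and 7.53% for scaffolds. The root-higher share was 5.67%, 7.37%, 8.20% and 5.82% in the same order. Of the 146 unigenes at 0 in aerial tissues with at least 20 root counts, 69 were leaf-named contigs and 46 were of the TR form.

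Alternative forms of the same assembled gene were biased the same way more often than unrelated unigenes. Of 33397 genes in the TR form, 4141 kept more than 1 unigene, and 2957 had at least 2 unigenes with enough counts to compare, which made 8818 pairs. In 737 pairs both members were at least 4-fold higher in the same part of the plant, and in 11 pairs they were at least 4-fold higher in opposite parts. The ratios of 441 pairs were at least 4-fold apart. Among 1000 random pairings of unigenes matched on counts, 66 to 126 pairs were biased the same way and 50 to 104 opposite ways. Forms of 1 gene share sequence, and the pairs of 1 gene are not independent, so the difference does not show joint regulation.

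The root values of the series table and of the root library file were different quantifications of the same unigenes. Across unigenes, log2(FPKM + 1) of the table's root column correlated with r = 0.81 with the root file and r = 0.43 with the aerial file. Over the 14857 unigenes with at least 50 root counts, the median ratio of table to file was 1.02, and after division by it 4464 unigenes (30.0%) differed by at least 1.5-fold, 2963 lower in the table and 1501 higher. The table listed 23295 unigenes at 0 and the root file 9466. Unigene42163 was at 1516 FPKM in the table and 873 FPKM in the file, and Unigene20578 at 2419 and 2159 FPKM. Unigene47044 and Unigene47043 were at 0 in both.

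**Figure D3:**
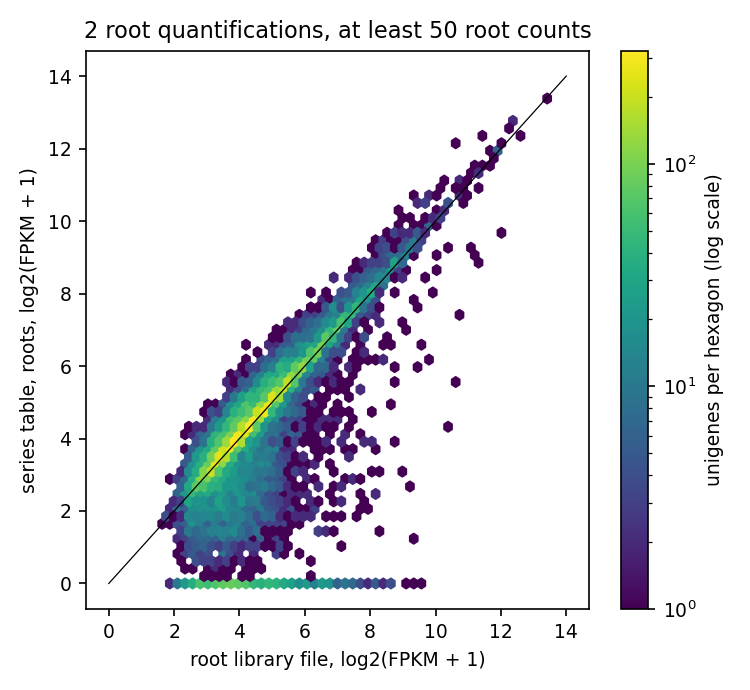
Each hexagon counts unigenes with at least 50 root counts (colour, log scale) by log2(FPKM + 1) of roots in the root library file (x axis) and in the series table (y axis); the line marks equal values. Most unigenes lie along the line, and those that the table lists at 0 lie on the bottom edge.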

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

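The test of counting noise in this part was chosen after its result was seen; the test of shared reads was not.

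Data outside the main comparison hold a signal for unigenes that the root library file lists at 0. The series table gives 55 of these a root FPKM above that of 3 counts in the root file, up to 15.6 FPKM. A single count was worth 1.58 times as much in the table, so some of these may rest on fewer than 3 counts there. The reverse was more frequent: 2106 unigenes with at least 20 root counts are at 0 in the table, 1 of them with 2969 counts.

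Where the root quantifications disagree, counting noise is argued against for well-covered unigenes, since 20.9% of the 1233 unigenes with at least 500 root counts differed by at least 1.5-fold (95% exact interval 18.7 to 23.3). The value of a single count was 1.58 times as high in the table as in the file (median over 350 lengths), so the table may rest on fewer reads, and noise stays open for low counts. Reads shared between similar unigenes were tested through unigenes of the TR form that have another unigene of the same TR number. Within count classes these differed by at least 1.5-fold in 51.5% of cases against 24.9% without such a sibling, a ratio of 2.07 (95% interval 1.94 to 2.21). The interval includes the bound of 2 set beforehand for shared reads as the source, so this explanation stays open. No biological explanation was tested, because the table's root column was matched, by name alone, to the same root sample.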

How the results depend on the processing

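Of 59 alternatives to the reported values, 32 stayed within 1.5 times the reported count (or within the interval of a share or correlation) and 27 moved further; the settings that sum counts per TR gene, leave out the most abundant or the discordant unigenes, recompute DESeq2 size factors over unigenes with at least 20 counts, or add a count minimum to FPKM were chosen after seeing the data. With library totals, the order of the aerial-higher and root-higher numbers turned at a fold of 2 and with at least 5 counts or no count minimum (2948 and 3093). That scaling left a median log2 ratio of 0.27 in favour of roots, and other scalings were not tried at these settings. Whether the turn at a fold of 2 comes from the scaling was therefore not tested. With at least 100 counts, 1423 unigenes were aerial-higher and 810 root-higher, with fewer unigenes compared. A fold of 2 gave 5338 and 6398, a fold of 8 gave 1328 and 1000, and an interval wholly past 4-fold gave 1543 and 1015. Unigenes at 0 in roots numbered 670 with at least 10 aerial counts and 49 with at least 100, and those at 0 in aerial tissues 427 and 11 at the same root counts. An FPKM of at least 5 was reached by 29556 unigenes in aerial tissues and 34144 in roots, and an FPKM of at least 1 with at least 10 counts by 33911 and 32061. The share of the 100 most abundant unigenes was 19.9% (aerial tissues) and 15.6% (roots) of expected counts, and 22.2% and 17.8% of TPM over unigenes of at least 500 bases; the 10 most abundant held 6.34% and 4.85%, and the 1000 most abundant 42.7% and 38.3%. The correlation between the libraries was 0.30 with a pseudocount of 0.1, 0.64 with at least 20 counts and 0.37 as Spearman's rho. Counting noise gave 0.388% of the 4911 unigenes called in either direction, so it does not account for the calls. Thinning the aerial library to the root total moved the ratio of root-higher to aerial-higher unigenes by a factor of 1.06. It kept 2542 of the 2787 aerial-higher and 1974 of the 2124 root-higher calls. Calls use CPM, whose expected ratios thinning leaves unchanged, so that factor does not show how many calls depth makes. Counts of at least 5 and no count minimum gave identical calls, because the floor of 3 counts already removes weaker ones. Summing by the gene identifiers of the files changes nothing, since each unigene has its own, and no library could be left out. The lists of pathway and marker genes were not run. Thinning gave 254 unigenes at 0 in roots and 177 at 0 in aerial tissues. Count minimums, folds, set sizes and scalings, which shift every ratio alike, change these counts by construction. Leaving out discordant unigenes reaches those with at least 50 root counts alone, and a count under 1 equals a count of 0 here, so neither speaks for stability. For the other settings the cause was not tested. No paired analysis was possible because each tissue had 1 library. Variation between plants cannot be measured here.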

Other observations

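The comparison of length classes within TPM classes, and the test of other organisms among unigenes with at least 100 root counts, were chosen after related values were seen; the other tests in this part were not.

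The aerial-higher share had no fixed relation to length. With at least 200 counts it was 11.7% under 1000 bases and 6.46% at 2000 bases and over. At a mean of at least 20 and under 50 TPM, 10.1% of unigenes under 1000 bases were root-higher against 3.51% of those of 2000 bases and over, and 9.31% against 7.79% were aerial-higher. At a mean of 100 TPM and over the root-higher shares were 11.5% and 5.65%, while the aerial-higher shares were 13.7% and 22.6%, the last of 124 long unigenes. The root-higher share was higher in short unigenes in each of these classes.

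Several explanations of the shortness of root-higher unigenes were tested. Counting noise in short unigenes is argued against: with at least 200 counts, the root-higher share was 9.83% under 1000 bases and 2.72% at 2000 bases and over, a ratio of 3.62 (95% interval 2.83 to 4.63). A length trend common to all unigenes is argued against as the whole cause, because the ratio was 3.82 (95% interval 2.83 to 5.16) after each length class was centred on its median. After that centring the root-higher shares were 6.96% and 1.82%, and the aerial-higher shares 14.4% and 8.25%. Short unigenes were thus more often biased in both directions. RNA of organisms living on the roots was predicted to leave short root-higher unigenes at 0 in aerial tissues. This held for 9.46% of the 1004 root-higher unigenes under 1000 bases (95% exact interval 7.72 to 11.4), too close to the bound of 10% to decide. It held for 2.82% of the 213 with at least 100 root counts (95% exact interval 1.04 to 6.03). A few stray aerial reads would end a 0, more readily at high root counts. The lower share therefore does not decide, and this explanation stays open. A difference between the organs in which short transcripts they express, and assembly of root transcripts in pieces, stay open and were not tested.

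The leaf-named contigs raised the hypothesis that this form was assembled from aerial reads alone, which was predicted to leave it poor in root-higher transcripts. The predicted shortage was not found. Standardised to the lengths of the TR form, 7.88% of leaf-named contigs were root-higher against 5.67% of the TR form, a ratio of 1.39 (95% interval 1.26 to 1.53). A contig assembled from aerial reads can still be higher in roots, so the ratio does not decide how this form was assembled. Leaf-named contigs at 0 in aerial tissues with at least 20 root counts numbered 69, and those at 0 in roots with at least 20 aerial counts 82. Of all leaf-named contigs 12.3% were at 0 in aerial tissues and 11.8% at 0 in roots, against 8.93% and 10.6% of the TR form. Assembly from these aerial reads alone is argued against for the 69, unless their aerial reads were left out or assigned to similar unigenes. For the other leaf-named contigs it stays open.

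A further hypothesis was that alternative forms of 1 assembled gene change independently between the organs. It was not borne out: 11 of 8818 pairs were at least 4-fold higher in opposite parts of the plant, below the 50 to 104 of 1000 random pairings. Splitting of shared reads in fractions would pull the ratios of such forms together, and the whole counts argue against it. How shared reads were otherwise handled is not known here, and its effect was not separated from joint regulation. The 11 pairs that do part may be worth following for organ-specific forms. The handling of shared reads could also set forms apart, and neither this nor counting error was tested for these pairs.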
